A study of Rattus norvegicus with 200 samples.

How the data were processed

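RNA was sequenced in bulk from the brains of adult male rats of the Wistar strain, an outbred laboratory stock, in libraries that the labels call microglia, the resident macrophages of the brain. The diet was chow or was high in fat (HFD), with food always present (ad libitum), in the dark phase only or in the light phase only. Libraries were made at 6 Zeitgeber times (ZT), 4 h apart, ZT0 being lights on, with 5 to 7 libraries per group and time. The 6 groups of diet and feeding schedule held 33 or 34 libraries each, 200 in all. The labels do not say that every library came from a separate rat, so p-values measure the spread between these libraries.

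Per the labels' protocols, RNA was extracted with a spin column kit, messenger RNA was enriched on beads, and strand-specific libraries were sequenced as DNA nanoballs. The genome build was Rnor_6.0, per the submitters' processing notes. The aligner and the counting program are not given in the sources used here. The authors deposited a table of expected counts for 20361 genes, of which 8.03% of the entries were not whole numbers, and these estimated counts were not normalised. The authors also deposited a table of FPKM values, normalised by transcript length and library size, for 17611 genes. Expected counts were rounded to whole numbers before every count test, where the design written before the data were examined had foreseen raw counts. No genome of that build was used here, so genes are named by the symbols in the tables and no coordinates are given. Genes that share reads with close copies, such as the haemoglobin genes, the major histocompatibility genes of the RT1 region and Myh9l1, are uncertain to the extent that the estimation divided reads between copies.

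Total counts ran from 3.78 to 11.64 M per library, M standing for 10 to the power of 6, with a median of 7.55 M. No pair of libraries had identical counts. The closest of 19900 pairs differed by a chi-square of 2.35 per degree of freedom, so no pair agreed within sampling noise and every library was counted once.

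Counts were scaled by the trimmed mean of M values (TMM) and tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 and a Benjamini-Hochberg adjusted p under 0.05. Genes with too few counts were removed by edgeR's filter over the 6 groups, which left 14393 genes. Pairs of groups were compared with time as a factor, using only the libraries of both groups. Interactions of diet and schedule used 4 groups. Rhythms were tested within each group as a cosine and sine of 24 h period, and a difference in rhythm as the interaction of both terms with the group. A shift in clock phase was computed as the amplitude-weighted angle between the cosine coefficients of 12 clock genes on log2 CPM with a prior count of 2, in hours, with a two-sided permutation test of 100000 resamples within times and 10000 bootstrap draws, and adjusted over 5 comparisons. Phases and bootstraps ran in Python 3.11.15 with numpy 2.4.6. CPM values are counts per M counts of the TMM-scaled library. Log2 fold changes (log2FC) carry the standard error (SE) of the fit, and means carry the standard deviation (SD).

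Gene lists, comparisons, tests, the rule for named genes and most alternatives were fixed before the data were examined. Of 36 lists of pathways, cell type markers and quality genes, 34 had enough measured members to be tested, with limma 3.58.1's camera at a preset correlation between genes of 0.01 and adjustment over the lists within a comparison. Of 374 such tests, 128 passed the threshold and 0 passed with an estimated correlation, where the lowest adjusted p was 0.118. With marker scores of other cell types in the model 72 passed, 43 of them the same lists and direction and 5 the same lists in the opposite direction.

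Named genes were chosen by rule. For the diet effect under ad libitum feeding and the schedule effects against ad libitum they were the 8 genes with the largest log2FC in each direction among those past the threshold with a mean of at least 5 CPM, a gene symbol and the same sign of the difference in at least 5 of the 6 times. For other comparisons it was 4 in each direction. For each list described, up to 4 members with the smallest adjusted p were named, or up to 2 where none passed. For rhythms the core clock genes were named, and the 8 others per group with the largest peak-to-trough change.

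The tests were checked on simulated counts with 200 changed genes each. Simulated libraries were independent and every gene had a dispersion of 0.04, so the shares below need not hold for the real libraries. For the diet effect under ad libitum feeding, over 14393 genes, 98.5% of genes changed by 1.5-fold and 98.5% of those changed by 2-fold were recovered, and 2.23% of calls were false. For rhythms in chow ad libitum, 3% of genes with a peak-to-trough change of 1.25-fold, 37.3% at 1.5-fold and 84.8% at 2-fold were recovered. For the difference in rhythm by diet under ad libitum feeding the shares were 0%, 14.9% and 65.2%, so weak differences would be missed.

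Alternatives planned before the data were examined covered DESeq2 1.42.0, another scaling, gene filters, FPKM with limma after adding 0.1, marker scores of 5 other cell types or an immediate early score as covariates, 1 fit to all libraries, title numbers as a spline, HFD ad libitum libraries with title numbers above 46 only, libraries left out for standing apart, and each time left out. The titles carry a running number, whose meaning the labels do not give. Added after the data were seen were fits with runs of neighbouring title numbers as the unit, transcript length offsets, and fits without libraries whose Per2 stood apart. Values of 4 genes are not reported here and were left out of the gene totals across alternatives.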

Results

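The data asked how a high-fat diet and the time of feeding shape gene expression over the day in cells isolated as rat microglia. The median total count per library was 7.32 M in chow ad libitum (5.05 to 10.16, n = 34), 7.57 M in chow dark feeding (4.75 to 9.42, n = 33) and 7.95 M in chow light feeding (4.82 to 10.1, n = 33). It was 7.36 M in HFD ad libitum (3.78 to 10.78, n = 34), 7.96 M in HFD dark feeding (4.83 to 11.64, n = 33) and 7.57 M in HFD light feeding (4.82 to 11.37, n = 33). The titles fell into 2 numbered series, 1 per diet, and 0 series held both diets, so diet and any processing batch that followed the series cannot be told apart. Within HFD, 28 of 34 ad libitum libraries had title numbers up to 46, while every dark and light feeding library lay above 46. Libraries of the same group and time correlated at 0.209 on average when their title numbers were 1 to 2 apart and at 0.018 when more than 20 apart, after group and time means were removed.

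Markers of oligodendrocytes and neurons stood above markers of microglia in libraries labelled microglia. Mbp, myelin basic protein, averaged 3471.3 CPM over all libraries. The median of 12 oligodendrocyte markers was 461 CPM in chow ad libitum and 517 CPM in HFD ad libitum, and that of 15 neuron markers was 124 and 129 CPM. The median of 21 homeostatic microglia genes was 45.9 and 39.5 CPM in the same groups. Astrocyte markers had medians of 61.7, 70.9 and 81.8 CPM in chow ad libitum, dark and light feeding and of 59.1, 44 and 46.2 CPM in the HFD groups in the same order. Endothelial markers had medians of 8.89, 9.37 and 10.7 CPM on chow and 6.75, 5.87 and 5.35 CPM on HFD. The neuron median was at least 2.7 times the microglia median in each of the 6 groups.

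**Figure D1:**
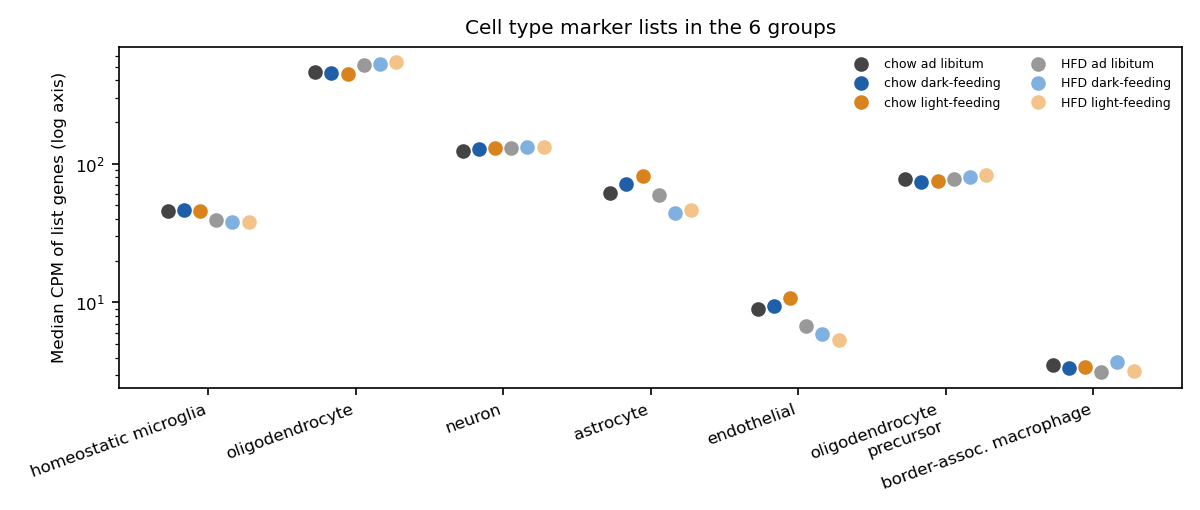
Median CPM (log axis) of the members of 7 marker lists in each of the 6 groups of diet and feeding schedule, with 1 point per list and group. The oligodendrocyte medians lie between 445 and 537 CPM and the homeostatic microglia medians between 37.8 and 46 CPM.

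HFD was compared with chow under ad libitum feeding to ask what the diet changed when food was always present. Most red blood cell genes and some genes of the immediate early response, of ribosomal proteins and of the microglial homeostatic state were lower on HFD, and some genes of fatty acid synthesis and oligodendrocytes were higher. These lists passed by camera and lost their call at adjusted p = 0.825 with an estimated correlation. Scd, a stearoyl-CoA desaturase that makes monounsaturated fatty acids, rose from 14.1 ± 2.72 to 18.3 ± 3.43 CPM (SD, n = 34 each; log2FC 0.37, SE 0.06, adjusted p = 7.8e-05). Its brain paralogue Scd2 rose from 2020 ± 410 to 2410 ± 277 CPM (log2FC 0.26, SE 0.05). Junb, an immediate early transcription factor, fell from 14.6 ± 5.31 to 9.7 ± 2.26 CPM (log2FC -0.60, SE 0.1, adjusted p = 7.5e-05). Cst3, the abundant cystatin C of resting microglia, fell from 924 ± 337 to 721 ± 148 CPM (log2FC -0.37, SE 0.1, adjusted p = 0.0067), and Tmem119, a microglial surface protein, fell by 0.28 (SE 0.08).

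In all, 2908 of 14393 genes passed an adjusted p of 0.05 for this comparison, 1358 higher and 1550 lower on HFD, and 35 of them differed by at least 1.5-fold. Among the largest rises under the rule for named genes, which asks for a mean of at least 5 CPM, were Gjc3 (log2FC 0.39, SE 0.08), a connexin of myelinating glia, and Clmn, Gng8, Scd, Atn1, Zbtb16 and Fam206a at 0.35 to 0.37. The largest falls under that rule were Myh9l1 (log2FC -1.68, SE 0.57, adjusted p = 0.028), Hba2 (-1.10, SE 0.24), Hba1 (-1.09, SE 0.24), Hbb (-1.02, SE 0.25), Hbb-b1 (-1, SE 0.24), Fos (-0.80, SE 0.27) and Capns1 (-0.61, SE 0.2). Haemoglobin levels varied widely, Hba1 being 274 ± 291 CPM on chow and 124 ± 101 CPM on HFD.

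Of 21 homeostatic microglia genes 7 fell and 0 rose (12 fell adjusted over the list alone; camera adjusted p = 0.00205). Of 20 immediate early genes 8 fell (13 over the list alone; 0.000144), of 77 cytosolic ribosomal protein genes 30 fell (46; 4.93e-12), of 72 nuclear genes of oxidative phosphorylation 19 fell (22; 4.37e-06), and of 8 erythrocyte genes 7 fell (8; 1.2e-05). Of 24 glycolysis genes 3 rose and 9 fell (3 and 12; 0.00724), Pfkl, the liver-type phosphofructokinase, falling by 0.28 (SE 0.04) and the regulatory kinases Pfkfb2 and Pfkfb3 rising by 0.14 and 0.15. Of 23 NF-kB and cytokine genes 6 fell (6; 0.0279), among them Nfkbia (-0.23, SE 0.08), and of 26 interferon response genes 3 fell (1; 0.0115), among them Oasl (-0.78, SE 0.18). Of 12 fatty acid synthesis genes 3 rose (3; 0.0405), and of 12 oligodendrocyte markers 3 rose (3; 0.00227). Each of these 10 lists lost its call at adjusted p = 0.825 with an estimated correlation.

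Lists without a call also held changed members, where 1550 of all 14393 genes fell and 1358 rose. Of 22 disease-associated microglia genes 3 fell (1 adjusted over the list alone; camera adjusted p = 0.362), among them Trem2, a lipid-sensing microglial receptor (-0.32, SE 0.09), and Apoe, a lipid carrier (-0.33, SE 0.12). In the phagosome and lysosome list 4 of 33 rose and 8 fell (5 and 8; 0.247), the complement genes C1qb and C1qc falling by 0.36 and 0.37. Of 11 LXR targets 4 rose and 2 fell (4 and 2; 0.118), Abca1, a cholesterol exporter, rising by 0.26 (SE 0.07). Of 14 genes of MHC class II presentation 2 fell (1; 0.509). Cldn5, the tight junction claudin of brain endothelium, fell from 10.7 ± 7.61 to 6.97 ± 3.03 CPM (log2FC -0.58, SE 0.19), and 2 of 12 endothelial markers fell (2; 0.0519). With runs of neighbouring title numbers as the unit, 0 genes were called by edgeR for this comparison, 3073 having an unadjusted p under 0.05. The median size of the log2FC of the 2908 genes was then 0.177, against 0.155 with libraries, so smaller fold changes did not end these calls. Runs sum the same libraries, so a kept size does not tell whether run structure made the differences. With marker scores of other cell types in the model 1083 were called. Without ZT14 the count was 1390 and without ZT18 it was 874, and FPKM moved the split to 1113 higher and 1928 lower.

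Under dark feeding more genes were called for diet than under ad libitum feeding. The direct test of that difference, the interaction of diet with dark feeding, passed for 126 genes. HFD ad libitum libraries mostly held lower title numbers than HFD dark feeding libraries, so title order cannot be told apart from the schedule in it. Most listed genes of astrocytes, blood vessels and oxidative phosphorylation were lower and most oligodendrocyte markers higher on HFD. Cldn5 fell from 13 ± 5.89 to 6.21 ± 1.85 CPM (SD, n = 33 each; log2FC -1.05, SE 0.15, adjusted p = 1.4e-07), Tagln, an actin-binding protein of smooth muscle, fell by 0.95 (SE 0.13), and Igfbp2, a carrier of insulin-like growth factors, fell by 0.98 (SE 0.13). Pclo, a presynaptic scaffold, rose from 170 ± 75.9 to 254 ± 99.7 CPM (log2FC 0.56, SE 0.12), and Pigm (0.86, SE 0.16), Fut9 (0.55, SE 0.09) and RT1-Ba, an MHC class II chain (0.53, SE 0.11), rose as well. In all 6588 genes were called, 3248 higher and 3340 lower, 222 of them by at least 1.5-fold. Of 72 oxidative phosphorylation genes 63 fell and 1 rose (65 and 1 adjusted over the list alone; camera adjusted p = 3.88e-19, and adjusted p = 0.365 with an estimated correlation), Uqcrq from 10.4 ± 3.42 to 6.61 ± 1.47 CPM. Of 14 astrocyte markers 12 fell and 1 rose (12 and 1; 1.24e-05), Gfap, the astrocyte intermediate filament, from 81.7 ± 28.7 to 46.5 ± 12.3 CPM, of 8 mural cell markers 7 fell and 1 rose (7 and 1; 8.65e-05) and of 12 endothelial markers 10 fell (10; 4.67e-05), each at adjusted p = 0.365 with an estimated correlation. Of 21 homeostatic microglia genes 14 fell (16; 6.56e-06), of 77 ribosomal protein genes 64 fell (66; 1.22e-13), both at adjusted p = 0.461 with an estimated correlation, and of 12 oligodendrocyte markers 8 rose (8; 0.00575, and adjusted p = 0.584 with an estimated correlation). With runs as the unit 2966 genes were called and with marker scores 1560. FPKM gave 2337 higher and 4362 lower, and length offsets 3109 higher and 2487 lower.

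Under light feeding most astrocyte and oxidative phosphorylation genes and some vessel genes were lower on HFD. Some cholesterol synthesis genes and single genes of antigen presentation were higher. Itih3, a hyaluronan-binding protein, fell from 164 ± 73.7 to 65.8 ± 18.6 CPM on HFD (SD, n = 33 each; log2FC -1.26, SE 0.12, adjusted p = 5.3e-12), Etnppl, a phospholyase of astrocytes, fell by 1.34 (SE 0.13), and Cldn5 fell by 1.28 (SE 0.15). Genes of antigen presentation rose among the members, RT1-Da from 32.7 ± 17.4 to 51.1 ± 17.6 CPM (0.63, SE 0.14), RT1-Ba by 0.73 (SE 0.14) and their transactivator Ciita by 0.61 (SE 0.14). Of 14 MHC class II genes 6 rose and 2 fell (6 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.15). Of 23 cholesterol synthesis genes 13 rose and 4 fell (13 and 4; 0.00604, and adjusted p = 0.452 with an estimated correlation). In all 7237 genes were called, 3517 higher and 3720 lower, 306 by at least 1.5-fold. Of 72 oxidative phosphorylation genes 58 fell and 1 rose (60 and 3; 1.1e-11, and adjusted p = 0.452 with an estimated correlation). Of 14 astrocyte markers 12 fell and 2 rose (12 and 2; 1.11e-05), and of 8 mural cell markers 7 fell (7; 1.59e-05). Of 21 homeostatic microglia genes 13 fell (13; 0.000742), and of 12 oligodendrocyte markers 8 rose (8; 0.00604). Of 77 ribosomal protein genes 55 fell and 1 rose (60 and 1, 3.08e-07). From the astrocyte to the ribosomal list adjusted p was 0.427, 0.259, 0.634, 0.639 and 0.684 with an estimated correlation. The median log2FC was -0.17 in the shortest 10% and 0.09 in the longest 10% of transcripts, and -0.18 and 0.12 under dark feeding. Whether this length trend made the list falls under either schedule was not tested. With marker scores 1455 genes were called and the ribosomal list turned higher (camera adjusted p = 0.000148), while FPKM gave 2737 higher and 4557 lower and length offsets 3678 higher and 2916 lower.

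**Figure D2:**
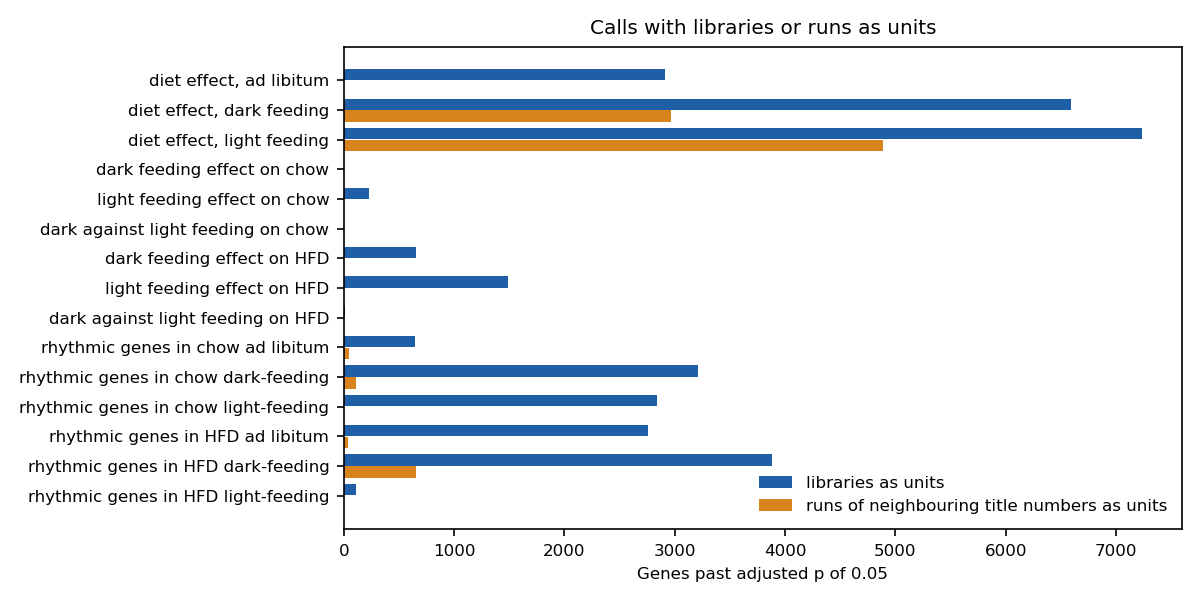
Number of genes past an adjusted p of 0.05 in 9 pairwise comparisons and 6 tests of rhythm, with each library as a unit and with runs of neighbouring title numbers summed into 1 unit. The diet effect under light feeding has 7237 genes with libraries and 4887 with runs as units, and all 6 schedule comparisons have 0 with runs.

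Dark feeding was compared with ad libitum feeding on chow to ask what restriction to the active phase of the rat changed without an obesogenic diet. No single gene passed. Smooth muscle genes lay higher in the dark feeding libraries without passing, Tagln at 9.1 ± 4.01 against 6.33 ± 2.69 CPM (SD, n = 33 and 34; log2FC 0.50, SE 0.14, adjusted p = 0.37) and Acta2 at 4.45 ± 4.14 against 2.6 ± 1.91 CPM. The mural cell list as a whole was higher (0 of 8 members past, 1 adjusted over the list alone; camera adjusted p = 0.0054), as was oxidative phosphorylation (0 of 72; 0 over the list alone; 3.04e-06), both at adjusted p = 0.86 with an estimated correlation. The purinergic receptors P2ry12 and P2ry13 of resting microglia gave log2FC of -0.09 and -0.12 (SE 0.07 and 0.08), and 0 of 21 homeostatic genes passed (0; 0.965). By edgeR 0 genes were called and 1707 had an unadjusted p under 0.05, and DESeq2 called 1, as did edgeR without the libraries whose Per2 stood apart. Without ZT10 or ZT18 it called 1 and 2.

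Light feeding on chow, restriction to the resting phase of the rat, went with few called genes, some of them astrocyte genes with higher levels. Gli1, a transcription factor of hedgehog signalling, rose from 3.92 ± 1.96 to 6.21 ± 3.26 CPM (SD, n = 34 and 33; log2FC 0.60, SE 0.16, adjusted p = 0.044). Gja1, the main astrocyte connexin, rose from 26.9 ± 12.1 to 37.4 ± 11 CPM (0.46, SE 0.12). Col1a1, a collagen chain, rose from 13.3 ± 5.37 to 18.9 ± 5.33 CPM (0.48, SE 0.12), and Calb1, a calcium buffer of Purkinje cells, rose from 16.7 ± 5.47 to 22.7 ± 7.85 CPM (0.46, SE 0.12). Idi1, an isomerase of the cholesterol pathway, fell from 29.2 ± 8.06 to 23.3 ± 4.96 CPM (-0.34, SE 0.08). The other named rises were Aox1, Slc13a4, Slc7a10, Gdf10 and Car8 (0.46 to 0.54), and the other named falls were Klhl25, Sowahb, Peak1, Fem1c, Tmem126a, Zfp518b and Klhl9 (-0.36 to -0.27). In all 230 genes were called, 73 higher and 157 lower, 3 by at least 1.5-fold. Of 14 astrocyte markers 2 rose (8 adjusted over the list alone; camera adjusted p = 3.47e-07) and of 8 mural cell markers 0 rose (6; 0.000206), both at adjusted p = 0.416 with an estimated correlation. Of 72 oxidative phosphorylation genes 1 rose (1; 1.11e-05, and adjusted p = 0.912 with an estimated correlation) and of 15 neuron markers 0 rose (4; 0.0159, and adjusted p = 0.561 with an estimated correlation). By edgeR 0 of 21 homeostatic microglia genes (0; 0.775) and 1 of 23 cholesterol synthesis genes passed (1; 0.897). By edgeR 0 genes were called with runs of neighbouring title numbers as the unit, with title number as a spline and without ZT10 or ZT22 (672, 896, 1902 and 2067 at an unadjusted p under 0.05). The median size of the log2FC of the 230 genes, 0.184, was then 0.168, 0.082, 0.179 and 0.181, so only the spline brought it down by more than 0.02 among these 4. It called 2 with marker scores or without ZT2 and 1 without ZT6, but 1382 without ZT14 and 1118 without ZT18. DESeq2 called 410, and FPKM turned the split to 44 higher and 17 lower.

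Dark and light feeding on chow were also compared with each other, and no single gene passed. The T and NK cell list as a whole was higher under dark feeding (0 of 15 members past, 1 adjusted over the list alone; camera adjusted p = 7.58e-08) and the astrocyte list lower (0 of 14; 0; 9.79e-05), both at adjusted p = 0.735 with an estimated correlation. By edgeR 0 genes were called and 613 had an unadjusted p under 0.05, and DESeq2 called 0, while without ZT14 edgeR called 3.

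Dark feeding on HFD was compared with ad libitum HFD to ask whether restriction to the active phase alters the HFD profile. Some genes of cytotoxic lymphocytes and single MHC class II chains were higher, and some genes of astrocytes, mural cells and oxidative phosphorylation were lower, than in ad libitum libraries, which mostly held other title numbers. The lymphocyte, astrocyte, mural cell and oxidative phosphorylation lists lost their calls at adjusted p = 0.22 to 0.522 with an estimated correlation. Prf1, the pore-forming perforin, rose from 3.89 ± 2.14 to 6.67 ± 4.3 CPM (SD, n = 34 and 33; log2FC 0.76, SE 0.19, adjusted p = 0.015), and RT1-Bb rose from 32 ± 12.8 to 44.7 ± 22 CPM (0.42, SE 0.12). Gfap fell from 62.7 ± 25.4 to 46.5 ± 12.3 CPM (-0.43, SE 0.11), Aqp4, the astrocyte water channel, from 55.6 ± 18.5 to 41.4 ± 10.7 CPM (-0.42, SE 0.1), and Igf2, a growth factor of the meninges, from 31.4 ± 10.9 to 22.4 ± 6.81 CPM (-0.50, SE 0.11). Other named rises were Il2rb, Yme1l1, RT1-Db1, Clec10a, RT1-Da and Irs1 (0.34 to 0.55), and other named falls were Pcp4, Fmod, Gjb6, Nrgn and Igfbp2 (-0.47 to -0.43).

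In all 651 genes were called for dark feeding on HFD, 233 higher and 418 lower, 11 by at least 1.5-fold. Of 15 T and NK cell markers 3 rose (4 adjusted over the list alone; camera adjusted p = 0.000315). Of 14 MHC class II genes 3 rose (6 rose and 2 fell; 0.165). Of 14 astrocyte markers 6 fell (12; 2.96e-09), and of 8 mural cell markers 4 fell and Cspg4 rose (6 and 1; 0.000554). Of 72 oxidative phosphorylation genes 16 fell (29; 9.15e-14). Of 8 oligodendrocyte precursor markers 3 rose (5; 0.000525), and 0 of 21 homeostatic microglia genes fell singly (2; 0.000315). With an estimated correlation the lists that passed gave adjusted p = 0.522, 0.22, 0.243, 0.344, 0.344 and 0.522 in this order. The edgeR test called 0 genes with runs as the unit (1135 at an unadjusted p under 0.05), 1 with marker scores, and 38 against the 6 ad libitum libraries with title numbers above 46, of which 2 were among the 651 and for which Gfap gave 0.11 in place of -0.43. Against those libraries Gjb6, Nrgn, Igfbp2 and Acta2 turned to 0.0032, 0.021, 0.03 and 0.51, and Yme1l1 and Irs1 to -0.17 and -0.1. Title number as a spline gave 721, of which 125 were among the 651, and leaving out ZT2, ZT14 or ZT22 gave 303, 198 and 271.

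The light feeding libraries on HFD had higher levels of some genes of antigen presentation, lysosomes and cholesterol synthesis and lower levels of some astrocyte and vessel genes than the ad libitum libraries, which mostly held other title numbers. RT1-Bb rose from 32 ± 12.8 to 44.7 ± 14.3 CPM (SD, n = 34 and 33; log2FC 0.47, SE 0.11, adjusted p = 0.0028) and Prf1 from 3.89 ± 2.14 to 6.82 ± 4.44 CPM (0.77, SE 0.18). Ctsd, the lysosomal protease cathepsin D, rose from 326 ± 16.7 to 352 ± 21 CPM (0.11, SE 0.02, adjusted p = 0.00067). Gfap fell from 62.7 ± 25.4 to 46.8 ± 14.4 CPM (-0.43, SE 0.12), and Flt1, a receptor of vascular endothelial growth factor, from 7.6 ± 3.11 to 5.73 ± 2.16 CPM (-0.41, SE 0.13). Other named rises were Yif1b, Capns1, Il2rb, RT1-Db1, RT1-Da and Adra2c (0.38 to 0.79), and other named falls were Slco1a2, Tagln, Slc7a10, Fam107a, Slc14a1 and Itih3 (-0.45 to -0.38).

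In all 1490 genes were called for light feeding on HFD, 792 higher and 698 lower, 19 by at least 1.5-fold. Of 14 MHC class II genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.0188, and adjusted p = 0.909 with an estimated correlation). Of 33 phagosome and lysosome genes 8 rose (10; 0.000876, and adjusted p = 0.709 with an estimated correlation), and of 23 cholesterol synthesis genes 6 rose (12; 0.000876, and adjusted p = 0.396 with an estimated correlation). Of 8 oligodendrocyte precursor markers 4 rose (4; 0.000876, and adjusted p = 0.406 with an estimated correlation) and of 15 T and NK cell markers 3 rose (3; 0.032, and adjusted p = 0.909 with an estimated correlation). Of 14 astrocyte markers 3 fell (9; 0.00152, and adjusted p = 0.802 with an estimated correlation), of 8 mural cell markers 6 fell and 1 rose (7 and 1; 0.000876, and adjusted p = 0.396 with an estimated correlation). Of 72 oxidative phosphorylation genes 9 fell and 2 rose (11 and 3; 0.00188, and adjusted p = 0.909 with an estimated correlation). Among 21 homeostatic microglia genes 0 passed (0; 0.098). The edgeR test called 0 genes with runs as the unit, with title number as a spline and against the 6 ad libitum libraries above title number 46 (802, 1949 and 1909 at an unadjusted p under 0.05). The median size of the log2FC of the 1490 genes, 0.144, was then 0.12, 0.072 and 0.073. Against those 6 libraries the log2FC of Gfap, Flt1, Itih3 and Tagln turned to 0.33, 0.25, 0.37 and 0.16, of Acta2 and Pdgfrb to 0.92 and 0.26, and of Scarb2, Psap and Insig1, members of the lysosome and cholesterol lists, to -0.15, -0.0024 and -0.068. With marker scores it called 867, and without ZT22 401.

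Dark and light feeding on HFD differed in 12 genes, 5 higher and 7 lower under dark feeding. Degs1, a desaturase of ceramide synthesis, fell from 126 ± 9.85 CPM under light feeding to 112 ± 8.57 CPM under dark feeding (SD, n = 33 each; log2FC -0.17, SE 0.03, adjusted p = 0.0029). Smc1a, a cohesin subunit, fell from 103 ± 10.8 to 90.4 ± 7.4 CPM (-0.18, SE 0.03). Ubqln2 and Ubald1 fell by 0.19 each (SE 0.04), and Trip10, Arhgap4, Vcan and Mzt2b rose by 0.11 to 0.17. The glycolysis list was lower under dark feeding (0 of 24 past, 10 adjusted over the list alone; camera adjusted p = 9.28e-07, and adjusted p = 0.118 with an estimated correlation), with Gapdh at 352 ± 31.7 against 385 ± 35.5 CPM. So were the cholesterol synthesis list (0 of 23, 2 over the list alone; 9.18e-06, and adjusted p = 0.442 with an estimated correlation) and the phagosome and lysosome list (0 of 33, 3; 9.18e-06, and adjusted p = 0.712 with an estimated correlation). By edgeR 0 genes were called with runs as the unit, with marker scores, without ZT6 and in the fit to all libraries (712, 1307, 1157 and 1515 at an unadjusted p under 0.05). DESeq2 called 91, 49 higher and 42 lower, transcript length offsets gave 4 higher and 9 lower, FPKM gave 1 and 6, and title number as a spline gave 2, while leaving out ZT2, ZT10, ZT18 or ZT22 gave 94, 19, 6 and 62.

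The difference between restricted and ad libitum libraries was not the same on both diets for part of the genes. On HFD 28 of 34 ad libitum libraries had title numbers up to 46, and all restricted libraries lay above. Schedule and title order thus cannot be told apart in these interactions, for which no spline of title number was fitted. The interaction of diet with light feeding passed for 1366 genes, 818 with a higher and 548 with a lower log2FC on HFD than on chow. Of 14 MHC class II genes 5 were among the higher (6 adjusted over the list alone; camera adjusted p = 0.00356). Among the lower were 10 of 14 astrocyte markers (11; 1.51e-08) and 6 of 8 mural cell markers (7; 1.44e-06). With an estimated correlation these lists gave adjusted p = 0.606, 0.204 and 0.188 in this order. The interaction with dark feeding passed for 126 genes, 32 higher and 94 lower, 7 of the lower being oxidative phosphorylation genes (26 over the list alone, where 1 was higher; 1.58e-16, and adjusted p = 0.354 with an estimated correlation). Both counts were 0 by edgeR with runs as the unit (1026 and 589 at an unadjusted p under 0.05), where the median size of the called genes went from 0.249 to 0.192 for light and from 0.34 to 0.332 for dark feeding. Marker scores gave 147 and 56. Leaving out each time gave 109 (ZT2) to 2548 (ZT18) for light feeding, with 328, 683, 2114 and 831 without ZT6, ZT10, ZT14 and ZT22, and 1 (ZT2) to 925 (ZT18) for dark feeding, with 218, 24 and 3 without ZT10, ZT14 and ZT22. The fit to all libraries gave 272 higher and 340 lower for dark feeding, where FPKM gave 598 higher and 619 lower for light feeding.

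Whether restricted feeding moved the HFD profile back toward chow was asked by correlating, across genes, the diet effect with the schedule effect on HFD, with different HFD ad libitum libraries for each effect. Genes are not independent replicates in such a correlation. Over 100 splits the mean r was -0.029 for dark feeding (-0.214 to 0.145) and -0.033 for light feeding (-0.239 to 0.169), with covariances of -0.000437 and -0.000529. With the same ad libitum libraries in both effects r was -0.25 and -0.244 and the covariance -0.00371 and -0.00395, where unchanged groups simulated against shared libraries gave r of -0.486 and -0.503 and covariances of -0.00294 and -0.00307.

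Some clock genes were called rhythmic in every group with libraries as the unit. Under light feeding this depended on the fit, and runs of neighbouring title numbers as the unit gave 0 of 19 on either diet. Marker scores as covariates gave 0 of 19 on chow and 7 on HFD there. Dbp, an output transcription factor of the clock, ran from 31.2 ± 4.83 CPM at ZT2 (SD, n = 7) to 73.5 ± 10.9 CPM at ZT14 (n = 5) in chow ad libitum and peaked at ZT12.7 with a 2.33-fold fitted change (edgeR adjusted p = 5.9e-07). Arntl, which codes for the clock activator BMAL1, peaked at ZT3.6 in the same group (1.79-fold) and Per2, a repressor of that activator, at ZT17.5 (3.64-fold). Under dark feeding the fitted changes of Per2 were 4.66-fold on chow and 4.25-fold on HFD, and Ciart, a circadian repressor, changed 4.21-fold on HFD with its peak at ZT14.2. Under light feeding on chow Dbp ran from 40.3 ± 7.28 CPM at ZT6 (n = 5) to 56 ± 7.39 CPM at ZT18 (n = 6) with its peak at ZT18.3, and on HFD it changed 1.72-fold with its peak at ZT15.2. Per2 missed the threshold under light feeding on both diets (1.72-fold, adjusted p = 0.11 on chow; 1.77-fold, 0.1 on HFD). It had high means at both ZT2 and ZT18 there, 255 ± 17.9 CPM (n = 5) and 263 ± 95.9 CPM (n = 6) on chow, a shape that a 24 h cosine cannot follow. Of 19 clock genes 12, 14 and 10 were rhythmic in chow ad libitum, dark and light feeding (14, 17 and 10 adjusted over the list alone) and 15, 17 and 6 on HFD (19, 17 and 14).

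**Figure D3:**
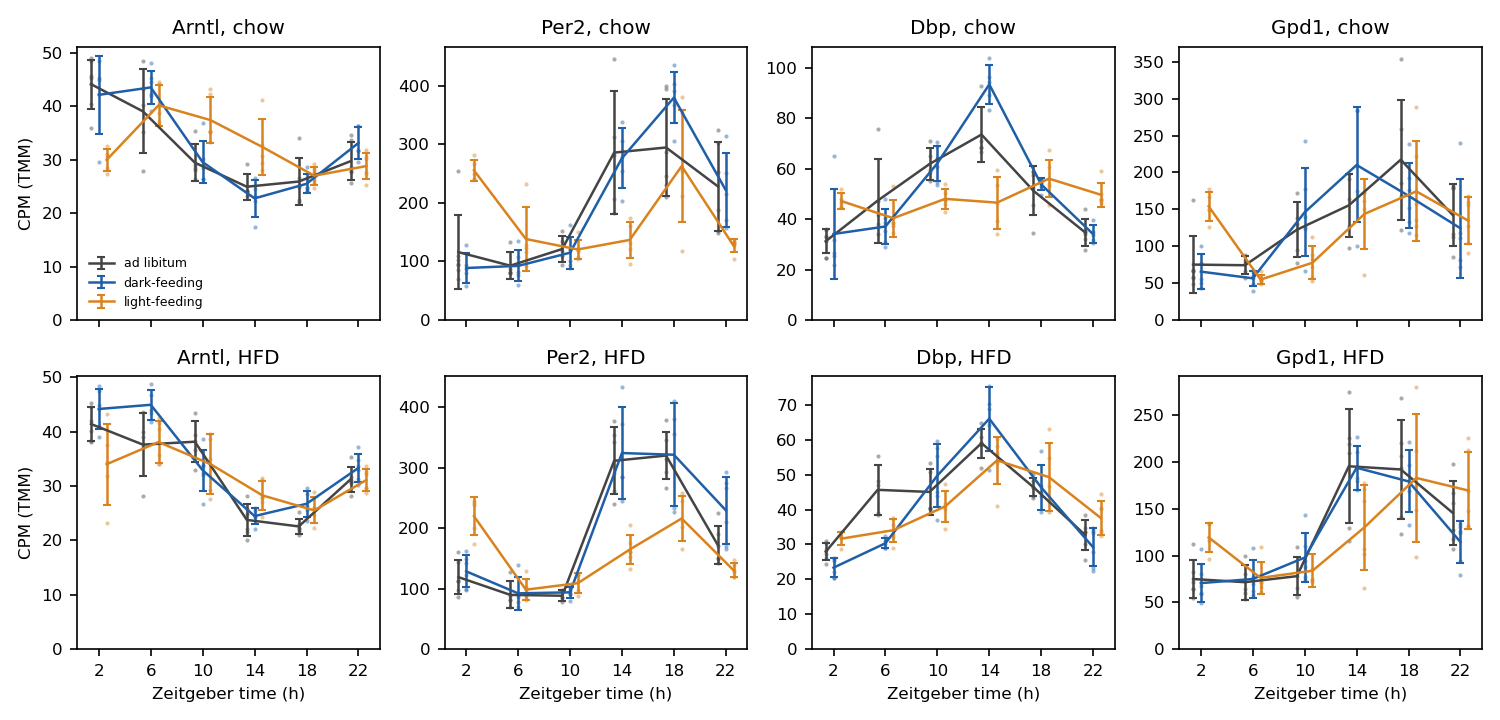
CPM of Arntl, Per2, Dbp and Gpd1 by Zeitgeber time (h), chow in the upper and HFD in the lower panels, coloured by feeding schedule. Points are libraries (5 to 7 per group and time), lines join means and bars are SD, and the curves of Dbp are flatter under light feeding.

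Genes of the glucocorticoid response cycled as well, the list passing in 5 of 6 groups. Any genes that this list shares with the clock list were kept in it. Outside the clock list Gpd1, a glycerol phosphate dehydrogenase induced by glucocorticoids, was named in all 6 groups, with 2.52- to 3.65-fold changes and peaks at ZT16.8 in chow ad libitum and ZT19.6 under light feeding on chow. Sgk1, a glucocorticoid-induced kinase, changed 2.41-fold in chow ad libitum (ZT16.2) and 2.85-fold under dark feeding on HFD (ZT16), and Zbtb16 and Pex11a peaked near the same hours. Npas4, a neuronal activity transcription factor, changed 7.54-fold under dark feeding on chow (ZT17.4) from 2.12 ± 1.11 CPM at ZT2 (n = 5) to 20.4 ± 15.9 CPM at ZT18 (n = 6). In HFD ad libitum Nr4a3, Nr4a2, Eomes and Spry4 changed 2.76- to 4.18-fold with peaks from ZT17.6 to ZT18.4. On chow, haemoglobin genes were rhythmic under dark feeding (ZT13.8 for Hba1) and light feeding (ZT1.8), but their SD exceeded their mean at the highest time, Hba1 being 1260 ± 1330 CPM at ZT14 (n = 5). S100a9, a neutrophil protein, was 24.3 ± 42.5 CPM at ZT2 (n = 5) under light feeding on chow. Myh9l1 was rhythmic under light feeding on HFD, with 28 ± 20.4 CPM at ZT18 and 0 counts in all 5 libraries of ZT2.

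In all 643 genes were rhythmic in chow ad libitum, 3208 under dark feeding and 2840 under light feeding on chow, and 2761, 3882 and 112 in HFD ad libitum, dark and light feeding. Of 16 glucocorticoid response genes 8 were rhythmic in chow ad libitum (9 adjusted over the list alone; hypergeometric adjusted p = 2.41e-06), 11 in chow dark feeding (12; 0.00138), 10 in HFD ad libitum (12; 0.000963), 12 in HFD dark feeding (13; 0.00145) and 3 in HFD light feeding (7; 0.00271). In chow light feeding 7 were rhythmic and the list did not pass (8, 0.0843). In HFD ad libitum 16 of 21 homeostatic microglia genes (17; 5.1e-07) and 10 of 14 MHC class II genes (12; 0.000211) were rhythmic, with mean peaks at ZT3.6 and ZT5.5. Near the same hours 6 of 11 monocyte markers (9, 0.0401, ZT5.6) and 35 of 77 ribosomal protein genes (60, 1.48e-06, ZT6.6) were rhythmic there. In HFD dark feeding 13 of 21 homeostatic genes (17, 0.00694, ZT5.1), 8 of 11 monocyte markers (9, 0.0138, ZT4.6) and 6 of 6 B cell markers (6, 0.00435, ZT5.7) were. Under light feeding on chow 10 of 12 oligodendrocyte markers (10; 4.45e-05) and 8 of 8 erythrocyte markers (8; 4.45e-05) were rhythmic, as were 7 of 8 oligodendrocyte precursor (8, 0.000652), 7 of 14 astrocyte (9, 0.0455) and 5 of 8 mural cell markers (6, 0.0455). Under dark feeding on chow 7 of 12 oligodendrocyte (9, 0.0357) and 6 of 8 erythrocyte markers (7, 0.0152) were. Lists of markers of other cells thus passed in 4 of the 6 groups, and single members of such lists in the other groups are not described here. With runs of neighbouring title numbers as the unit edgeR called 50, 108 and 0 genes on chow and 37, 654 and 0 on HFD, and 7, 8, 0, 4, 14 and 0 of the 19 clock genes in the same order. In the light feeding groups 1480 genes on chow and 1148 on HFD then had an unadjusted p under 0.05, and marker scores left 17 rhythmic genes in chow light feeding, where they gave 1082 in chow ad libitum and 1627 in HFD dark feeding. The low count in HFD light feeding depended on the fit, with 1175 genes for the 6 times as a factor and 415 by DESeq2. The factor gave 381 and 5052 in chow ad libitum and dark feeding and 1521 in HFD ad libitum, and DESeq2 1040 in chow ad libitum. Leaving out a time gave 227 (ZT2) and 84 (ZT18) in chow ad libitum, 367 (ZT6), 1729 (ZT10) and 1717 (ZT14) in chow light feeding. On HFD it gave 1815 (ZT14) and 848 (ZT18) in HFD ad libitum, 2478 (ZT18) in HFD dark feeding, and 7 (ZT10), 52 (ZT14), 39 (ZT18) and 694 (ZT22) in HFD light feeding.

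Under light feeding the fitted 24 h cosine of the clock genes came later and was smaller. On chow the panel of 12 clock genes was delayed by 4.31 h against ad libitum (95% bootstrap interval 3 to 6.1 h, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 5e-05), Arntl by 4.4 h and Dbp by 5.7 h. The amplitude was 0.46 times that of ad libitum (0.39 to 0.58, permutation adjusted p = 0.00192). On HFD the delay was 1.94 h (1.3 to 2.64 h, permutation p = 3e-05, adjusted p = 7.5e-05), Arntl by 0.8 h and Dbp by 2.1 h, and the amplitude ratio was 0.51 (0.46 to 0.58, adjusted p = 5e-05). In a test added after the shifts were seen, the HFD delay was shorter than the chow delay by 2.37 h (permutation p = 0.00396). That test permuted single libraries as independent and was not repeated with runs as the unit or with a time left out. The diets held separate title series, so a batch that followed them cannot be told apart from this difference. Dark feeding shifted the panel by 0.14 h on chow (-0.57 to 0.93 h, permutation p = 0.727) and 0.14 h on HFD (-0.25 to 0.53 h, permutation p = 0.584). The amplitude ratios were 1.27 (1.05 to 1.49, adjusted p = 0.0179) and 1.17 (1.08 to 1.26, adjusted p = 0.0052). The chow ratio was 1.14 without ZT18 (0.92 to 1.36, permutation p = 0.217) and 1.19 without ZT22 (0.96 to 1.39, permutation p = 0.104), and the HFD ratio 1.10 without ZT6 (1.01 to 1.2, permutation p = 0.0698). HFD shifted the ad libitum clock by 0.54 h (-0.15 to 1.3 h, permutation p = 0.221) with an amplitude ratio of 1.12 (0.97 to 1.27). Without ZT2 the light feeding delay was 2.05 h on chow (permutation p = 0.0196) and 0.61 h on HFD (permutation p = 0.129), and with runs as the unit the HFD delay was 1.73 h (permutation p = 0.0781). Without ZT22 the diet shift was 1.37 h (permutation p = 0.0111). An unweighted mean over the panel gave -0.22 h and -0.61 h for dark feeding on chow and HFD (permutation p = 0.724 and 0.117), and 4.14 h and 1.26 h for light feeding (permutation p = 1e-05 and 0.00282).

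**Figure D4:**
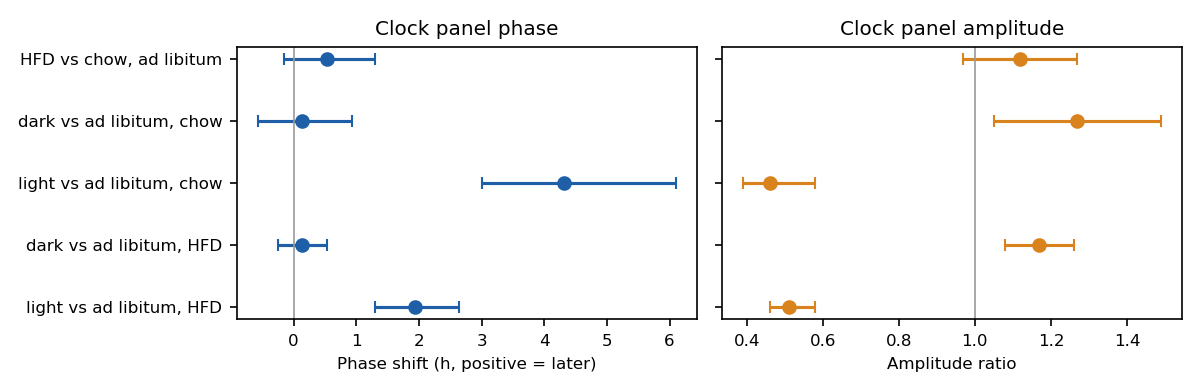
Shift of clock phase (h, left) and ratio of clock amplitude (right) in 5 comparisons from 12 clock genes, with points for the estimate and bars for 95% bootstrap intervals. Light feeding lies at 4.31 h on chow and 1.94 h on HFD with amplitude ratios of 0.46 and 0.51.

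In the cosine fit the tests of a difference in rhythm called more genes for light feeding than for dark feeding. Against ad libitum, 1632 genes changed their rhythm under light feeding on chow, 9 of 19 clock genes among them (14 adjusted over the list alone), Dbp with adjusted p = 1.3e-05 and Nr1d1, a clock repressor of Arntl, with adjusted p = 7e-04. On HFD 1517 genes did, again with 9 clock genes (12 over the list alone), Cry1 with adjusted p = 3.2e-05 and Per2 with adjusted p = 0.00069. Dark feeding changed the rhythm of 6 genes on chow, of 0 by edgeR without the libraries whose Per2 stood apart (2152 at an unadjusted p under 0.05), and of 2 on HFD, Srsf2 and Kcnab2, named after their values were seen. Of these, 0 were clock genes (0 and 4 over the list alone, the latter Dbp, Per3, Nr1d1 and Cry2). Between diets the rhythms of 1268 genes differed under light feeding, 3 clock genes among them (4 over the list alone), and of 0 genes by edgeR under ad libitum and dark feeding (2299 and 2306 at an unadjusted p under 0.05), although 93 differed under ad libitum feeding without the libraries whose Per2 stood apart. With runs as the unit edgeR gave 1 gene for light feeding against ad libitum on chow and 0 in the other 6 tests, where 289 to 1662 genes had an unadjusted p under 0.05. With marker scores the counts for light feeding were 839 on chow, 424 on HFD and 81 between diets, and those for dark feeding 16, 53 and 248. With the 6 times as a factor they were 1394, 1569 and 1186 for light feeding and 198, 11 and 1603 for dark feeding. Between diets both of these fits thus called more genes under dark than under light feeding, against 0 and 1268 in the cosine fit. No test compared the schedules in this, and relabelled libraries reached 1111 genes for diet under dark feeding in the cosine fit.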

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

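Chosen only after the result was seen were the fits with runs of neighbouring title numbers as the unit, the length offsets, the test of marker levels, the SE of the diet calls before and after covariates and the test of the phase difference between diets.

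Markers of other brain cells had higher levels than microglia markers in libraries labelled microglia. The neuron and oligodendrocyte marker medians were at least 2.7 times the homeostatic microglia median in all 6 groups, with Abca2 at 4466.5 CPM. Gene names attached to wrong rows are argued against by the mean correlation of 0.794 among the oligodendrocyte markers within group and time, where the highest of random lists gave 0.354. RNA from other brain cells in the samples may account for this, but levels of different marker genes restate the pattern and do not measure shares of RNA, so this stays open. Incomplete isolation, libraries of tissue and a biological explanation were not tested.

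The diet effect reached 2908, 6588 and 7237 genes under ad libitum, dark and light feeding. A trend with transcript length is argued against as the whole cause, since 72.4% of the calls stayed in the same direction under length offsets, although fold change rose with length across genes (Pearson r 0.311, 0.382 and 0.293 over genes, which are not independent replicates). With 5 marker scores as covariates 20.3% of the calls stayed. Under ad libitum feeding the median size of their log2FC fell from 0.155 to 0.103 while the median SE went from 0.042 to 0.04, so calls ended there mainly through smaller fold changes. Under dark and light feeding the log2FC fell from 0.194 to 0.098 and from 0.194 to 0.112, and the SE rose from 0.047 to 0.055 and from 0.045 to 0.067, so part of the loss came from a less precise estimate. A different share of other brain cells may account for the part that went with smaller fold changes. A lower share of microglia alone is argued against, because oligodendrocyte markers rose from 461 to 517 CPM and endothelial markers fell from 8.89 to 6.75 CPM under ad libitum feeding. With 0 title series holding both diets, a batch cannot be told apart from the diet, and an effect of the diet on the cells stays open as well.

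Rhythms reached 3882 genes in the group with the most, while libraries with neighbouring title numbers resembled one another. With times assigned to whole runs of neighbouring numbers at random, 9 of 100 assignments gave as many rhythmic genes as the real one in chow ad libitum (643 real, 5056 the highest other) and 17 in HFD light feeding (112 and 929), so run structure may account for those counts. Resemblance within single runs is argued against as the whole cause in chow dark feeding (1 of 100; 3208 and 2204), chow light feeding (4; 2840 and 4105), HFD ad libitum (3; 2761 and 3550) and HFD dark feeding (3; 3882 and 3915), although in 3 of these groups another assignment called more genes than the real one. These shares were not adjusted over the 6 groups. Libraries of the same diet but another group or time correlated at 0.14 when 1 to 2 title numbers apart and at -0.036 over 20 apart. Runs were thus not independent, and title order beyond single runs stays open there. For the clock genes resemblance within single runs is argued against as the whole cause, with 74 rhythmic calls over the 6 groups in the real assignment against 31 in the highest other (1 of 100). By group the highest other stayed under the real count in chow ad libitum (7 against 12), dark (11 against 14) and light feeding (8 against 10) and in HFD dark feeding (14 against 17), but equalled it in HFD ad libitum (15 against 15, 3 of 100) and passed it in HFD light feeding (8 against 6, 2 of 100). A daily rhythm in the cells, the biological explanation the design names, stays open for both kinds of genes.

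Relabelled libraries were tested in 100 splits per comparison, the real one included. These splits treat libraries as independent, which neighbouring title numbers contradict (mean correlation 0.209 at 1 to 2 apart against 0.018 over 20 apart), so they exclude only a chance draw of independent libraries. In that sense chance was excluded for the diet effects under ad libitum (1 of 100; 2908 real and 43 the highest other), dark (1; 6588 and 2) and light feeding (1; 7237 and 727), and for light feeding on chow (1; 230 and 1), dark feeding on HFD (1; 651 and 173), light feeding on HFD (1; 1490 and 47) and dark against light feeding on HFD (1; 12 and 5). With runs as the unit edgeR called 0 genes for these 4 schedule comparisons (672, 1135, 802 and 712 at an unadjusted p under 0.05) and for diet under ad libitum feeding (3073), and 2966 and 4887 for diet under dark and light feeding. The median size of the log2FC of the genes called with libraries went from 0.184 to 0.168, 0.166 to 0.173, 0.144 to 0.12 and 0.162 to 0.155 in these 4 and from 0.155 to 0.177 for diet, so fold changes stayed near their size with fewer units. Runs sum the same libraries, so this does not tell whether run structure made the differences. Title number as a spline took light feeding on chow and HFD to 0.082 and 0.072. In the same sense it was excluded for rhythms in chow ad libitum (1; 643 and 1), dark (1; 3208 and 2) and light feeding (1; 2840 and 8), in HFD ad libitum (1; 2761 and 64), dark (1; 3882 and 88) and light feeding (2; 112 and 176, another split calling more). Times assigned to whole runs did not exclude it for chow ad libitum and HFD light feeding. Where 0 genes were called by edgeR, 100 of 100 splits were as large by construction, which says nothing about chance: dark feeding on chow (0 and 1), dark against light feeding on chow (0 and 1553) and the rhythm difference by diet under ad libitum (0 and 72) and dark feeding (0 and 1111), with 1707, 613, 2299 and 2306 genes at an unadjusted p under 0.05. Splits that called 1553, 1111 or 665 genes point to a structure of the samples. Splits by title number alone called more genes than the real groups in each schedule comparison: 4404, 1778 and 887 on chow (0, 230 and 0 real) and 1269, 2462 and 825 on HFD (651, 1490 and 12 real). On HFD the title order placed 82.1%, 85.1% and 66.7% of the libraries as the real groups did, so for dark and light feeding against ad libitum the title and schedule splits were nearly the same, against 59.7%, 59.7% and 51.5% on chow.

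The difference by schedule or diet was not the same between groups by a direct test in the cases below. On HFD, ad libitum and restricted libraries mostly held different title numbers, so title order cannot be told apart from the schedule there. The interaction of diet with dark feeding had 126 genes (1 of 100 splits of single libraries; 23 the highest other), and that with light feeding 1366 genes (1 of 100; 66). With runs as the unit edgeR called 0 for both (589 and 1026 at an unadjusted p under 0.05). Rhythms differed between diets under light feeding in 1268 genes (1 of 100; 58). Against ad libitum, rhythms differed under dark feeding in 6 genes on chow (4 of 100; 665) and 2 on HFD (3 of 100; 4), and under light feeding in 1632 genes on chow (1 of 100; 302) and 1517 on HFD (1 of 100; 52). With runs as the unit edgeR called 1 gene for light feeding on chow and 0 in the other 4 of these rhythm tests (289 to 1662 at an unadjusted p under 0.05). The clock delay under light feeding was -2.37 h on HFD relative to chow (permutation p = 0.00396, single libraries permuted), and this test was not repeated with runs as the unit.

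Single libraries stood apart from the others of their group and time by Dixon's gap test, in 36 groups of group and time for each of 4 measures, where chance sets apart about 1 in 20. Total count set 1 apart, the chow dark feeding replicate 8 at ZT14 with 8.87 M (others 7.53 to 7.7). The score of other-cell markers, a mean log2 CPM, set 4 apart: HFD ad libitum replicate 28 at ZT6 with 4.38 (others 3.24 to 3.39), HFD dark feeding replicate 19 at ZT14 with 3.46 (3.06 to 3.13), chow dark feeding replicate 3 at ZT6 with 3.97 (3.65 to 3.74) and chow light feeding replicate 30 at ZT18 with 4.18 (3.28 to 3.53). The homeostatic microglia score set 2 apart, chow dark feeding replicate 5 at ZT10 with 5.52 (5.15 to 5.22) and chow light feeding replicate 30 at ZT18 with 5.9 (4.95 to 5.21). Per2 set 4 apart: chow ad libitum replicate 10 at ZT2 with 255 CPM (70.5 to 109) and replicate 13 at ZT6 with 134 CPM (80.2 to 86.9), and chow light feeding replicate 16 at ZT6 with 233 CPM (91.7 to 128) and replicate 8 at ZT22 with 105 CPM (128 to 135).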

How the results depend on the processing

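Chosen only after the data were seen were the fits with runs of neighbouring title numbers as the unit, with transcript length offsets and without libraries whose Per2 stood apart. Of the counts, shifts and correlations under each alternative, 276 stayed the same, 135 moved, 2 grew weaker and 1 stronger. Named genes of pairwise comparisons stayed the same in 3494 of 4493 cases, lost their call in 919, gained one in 36 and reversed in 44, and rhythms did so in 2185, 224, 43 and 12 of 2464. Where a value moved, the cause was not tested unless stated.

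With marker scores of 5 other cell types as covariates the numbers of genes were 1083, 1560 and 1455 for diet under ad libitum, dark and light feeding, 1 and 2 for dark and light feeding on chow, 1 and 867 for dark and light feeding on HFD, 0 for dark against light feeding on HFD (by edgeR, 1307 at an unadjusted p under 0.05). They were 56 and 147 for the interactions of diet with dark and light feeding. They were 1082, 17 and 1627 for rhythms in chow ad libitum, chow light feeding and HFD dark feeding, 248 and 81 for rhythm change by diet under dark and light feeding, 16 and 839 for rhythm change by dark and light feeding on chow, and 53 and 424 on HFD, and 72 list tests passed. With runs as the unit edgeR gave 0 for diet under ad libitum feeding, 2966 for diet under dark feeding, 0 for light feeding on chow, for dark, for light and for dark against light feeding on HFD and for both interactions, 50, 108 and 0 for rhythms on chow and 37, 654 and 0 on HFD in ad libitum, dark and light feeding, 1 for rhythm change by light feeding on chow and 0 for that by diet under light feeding, by dark feeding on both diets and by light feeding on HFD (289 to 3073 genes at an unadjusted p under 0.05 in the tests that gave 0). The clock delay by light feeding on HFD was then 1.73 h. Summing over runs left 12 to 17 units per group.

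Without outlying libraries the numbers were 1 for dark and 634 for light feeding on chow, 5 for dark against light feeding on HFD, 74 for the interaction with dark feeding, 850 for rhythm change by light feeding on chow and 21 by dark feeding on HFD. Without libraries whose Per2 stood apart they were 1 for dark feeding on chow, 93 for rhythm change by diet under ad libitum feeding and 0 for rhythm change by dark feeding on chow (edgeR, 2152 at an unadjusted p under 0.05). DESeq2 gave 1 and 410 for dark and light feeding on chow, 91 for dark against light feeding on HFD, and 1040 and 415 for rhythms in chow ad libitum and HFD light feeding. A fit to all 200 libraries gave 8 and 1026 for dark and light feeding on chow, 0 for dark against light feeding on HFD (edgeR, 1515 at an unadjusted p under 0.05) and 612 for the interaction with dark feeding. Genes with at least 1 count gave 65 for light feeding on chow and 4 for dark against light feeding on HFD, where more genes were adjusted for, and genes with a mean of at least 10 CPM gave 20 and 7 for rhythm change by dark feeding on chow and HFD, where fewer were. An immediate early score as a covariate gave 661 for light feeding on chow, 54 for dark against light feeding on HFD, 331 for the interaction with dark feeding and 2079 for rhythms in chow dark feeding. Length offsets gave 493 for light feeding on chow. FPKM gave 61 for light feeding on chow, 7 for dark against light feeding on HFD and 68 for the interaction with dark feeding. Title number as a spline gave 0 for light feeding on chow and on HFD (edgeR, 896 and 1949 at an unadjusted p under 0.05) and 2 for dark against light feeding on HFD, and HFD ad libitum libraries with title numbers above 46 alone, 6 in number, gave 38 and 0 for dark and light feeding on HFD (edgeR, 1909 for the latter). The 6 times as a factor gave rhythms of 381 and 5052 genes in chow ad libitum and dark feeding and of 1521 and 1175 in HFD ad libitum and light feeding, and rhythm changes of 1603 by diet under dark feeding and of 198 and 11 by dark feeding on chow and HFD. An adjusted p under 0.01 with a peak-to-trough change of at least 1.5-fold, a stricter limit by construction, left 69, 342 and 197 rhythmic genes on chow and 295, 611 and 5 on HFD.

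Of the list tests 0 passed with an estimated correlation. The correlation of the diet effect with the schedule effect was -0.182 and -0.14 for dark and light feeding over the genes called in the libraries used for the diet effect, and -0.25 and -0.244 with all HFD ad libitum libraries in both effects, where the shared libraries lower it by construction. With each of the 6 times left out the numbers ranged from 874 to 3011 for diet under ad libitum feeding, from 0 to 2 and 0 to 1382 for dark and light feeding on chow, from 0 to 3 for dark against light feeding on chow, from 198 to 753 and 401 to 1853 for dark and light feeding on HFD, from 0 to 94 for dark against light feeding on HFD, and from 1 to 925 and 109 to 2548 for the interactions with dark and light feeding. Rhythms ranged from 84 to 835 in chow ad libitum, 367 to 4139 in chow light feeding, 848 to 2818 in HFD ad libitum, 2478 to 3388 in HFD dark feeding and 7 to 694 in HFD light feeding, the clock shift by diet from -0.09 to 1.37 h and the delay by light feeding on HFD from 0.61 to 2.49 h.

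Some named genes reversed, given as log2FC. Fos was at 0.1 for diet under ad libitum feeding with the immediate early score, which contains it. Against HFD ad libitum libraries with title numbers above 46 alone, dark feeding gave Yme1l1 -0.17, Irs1 -0.1, Gjb6 0.0032, Gfap 0.11, Nrgn 0.021, Igfbp2 0.03, Pdgfra -0.22 and Acta2 0.51. Light feeding against the same libraries gave Slco1a2 0.032, Tagln 0.16, Gfap 0.33, Slc7a10 0.31, Fam107a 0.19, Flt1 0.25, Slc14a1 0.27, Itih3 0.37, Ndufa1 0.26, Ndufb2 0.086, Insig1 -0.068, Scarb2 -0.15, Psap -0.0024, Fgfr3 0.2, Gja1 0.13, Cspg5 -0.028, Gpr17 -0.14, Pdgfra -0.25, Cspg4 -0.16, Acta2 0.92 and Pdgfrb 0.26. With title number as a spline light feeding on HFD gave Tagln 0.041, Gfap 0.053, Flt1 0.078, Itih3 0.044, RT1-Ba -0.089, Insig1 -0.039, Scarb2 -0.089, Fgfr3 0.08, Gpr17 -0.085, Pdgfra -0.15, Cspg4 -0.06, Acta2 0.65 and Gzma -0.024, and dark feeding Acta2 0.13. The peaks of haemoglobin rhythms under dark feeding on chow moved by more than 6 h, with log2 peak-to-trough changes of 0.93, 0.9, 0.86 and 0.92 for Hba2, Hba1, Hbb-b1 and Hbb with marker scores and of 0.42, 0.37, 0.5 and 0.33 with the immediate early score, and of 0.53, 0.46, 0.42 and 0.57 without ZT14. With each time left out these changes ranged from 0.53 to 2.78, 0.46 to 2.76, 0.42 to 2.7 and 0.57 to 2.58. No named gene reversed under RLE scaling, DESeq2, FPKM or the filters on low counts. Of simulated 1.5-fold rhythms 37.3% were recovered in chow ad libitum, so weaker rhythms were mostly missed.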

Other observations

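Chosen only after the result was seen were the comparison of Per2 between schedules at each time, the distances between clock profiles and the count of libraries with Myh9l1.

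Genes of protein folding cycled in most groups. Of 14 cytosolic heat shock genes 6 were rhythmic in chow ad libitum (9 adjusted over the list alone; hypergeometric adjusted p = 0.000194), 10 in chow dark feeding (10; 0.00138), 10 in HFD ad libitum (12; 0.000211) and 9 in HFD dark feeding (10; 0.0215), with mean peaks from ZT17.1 to ZT18.9, while 4 (5; 0.664) and 0 (0; 1) were in light feeding on chow and HFD. Immediate early and dissociation genes, a mark of sample handling as well, were rhythmic at the same hours in chow dark feeding, 10 of 20 (10; 0.0336, ZT17.4), and did not pass in the other 5 groups (adjusted p of 0.148 or more). Stip1, a cochaperone of Hsp90, peaked at ZT18.81 in HFD ad libitum (log2 amplitude 0.26, edgeR adjusted p = 4.76e-07) and Ahsa1, an activator of that chaperone, at ZT17.61 (0.29). Of 21 genes of endoplasmic reticulum stress 7 were rhythmic in chow ad libitum (17; 0.000196), 10 in chow dark feeding (11; 0.0386), 14 in chow light feeding (16; 4.45e-05) and 10 in HFD ad libitum (12; 0.0143), while 10 in HFD dark feeding (13; 0.0897) and 0 in HFD light feeding (0; 1) did not pass as lists. Hsp90b1, the chaperone of that compartment, peaked at ZT20.55 in chow ad libitum (log2 amplitude 0.24, adjusted p = 0.001) and at ZT20.75 under light feeding on chow (0.30). Of 23 cholesterol synthesis genes 13 were rhythmic under dark feeding on chow (16; 0.00322) with a mean peak at ZT9.3, Cyp51 at ZT9.68, and 10 under light feeding on chow (11; 0.0455) with a mean peak at ZT18.5. Oligodendrocyte markers cycled at near hours, 7 of 12 under dark feeding (9; 0.0357, ZT10.3) and 10 of 12 under light feeding (10; 4.45e-05, ZT19.2). Of 6 B cell markers 6 were rhythmic under dark feeding on HFD (6; 0.00435) with a mean peak at ZT5.7, Cd79b averaging 2.52 CPM. Cytosolic ribosomal protein genes were rhythmic in 35 of 77 in HFD ad libitum (60; 1.48e-06, mean peak ZT6.6) and in 16 of 77 under light feeding on HFD (58; 1.87e-17, ZT12.3). Whether these lists differed in rhythm between groups was not tested. The hypergeometric test treats list members as independent, so its p are too small where members move together.

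Further lists separated the diets under restricted feeding. Of 24 glycolysis genes 15 fell and 3 rose on HFD under dark feeding (16 and 3 adjusted over the list alone; camera adjusted p = 1.24e-05, and adjusted p = 0.365 with an estimated correlation), Gapdh from 453 ± 90 to 352 ± 31.7 CPM (SD, n = 33 each) and Aldoa from 362 ± 61.8 to 286 ± 25.6 CPM. Of 18 antioxidant genes 10 fell (10; 0.00291, and adjusted p = 0.365 with an estimated correlation), Gpx4, a glutathione peroxidase of lipid hydroperoxides, from 71 ± 11.9 to 57.2 ± 4.32 CPM. Of 26 interferon response genes 13 fell under dark feeding (14; 0.00163, and adjusted p = 0.461 with an estimated correlation) and 10 under light feeding (7; 0.0207, and adjusted p = 0.702 with an estimated correlation), Ifi27 by 0.63 and 0.71 on the log2 scale, under light feeding from 5.24 to 3.23 CPM. Of 8 ependymal and choroid plexus markers 7 fell under light feeding (7; 0.00132, and adjusted p = 0.391 with an estimated correlation), Ttr, the transthyretin of the choroid plexus, from 96.4 ± 36.7 to 50.7 ± 22.8 CPM. Dark feeding on HFD against ad libitum raised 2 of 9 border-associated macrophage markers (3; 0.0191, and adjusted p = 0.522 with an estimated correlation), Mrc1 from 9.93 ± 2.74 to 12.5 ± 3.47 CPM (n = 34 and 33) and F13a1 from 2.57 ± 0.912 to 3.73 ± 1.53 CPM. With marker scores of 5 other cell types as covariates only glycolysis (adjusted p = 0.000359) and the interferon response under dark feeding (0.00505) still passed, against 0.574 for antioxidant genes, 0.934 for the interferon response under light feeding, 0.439 for the choroid plexus list and 0.9 for border-associated macrophages.

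Per2 was compared between restricted and ad libitum feeding at each time on each diet, in 24 two-sided exact permutation tests. These treat libraries as independent, although all 6 HFD ad libitum libraries at ZT2 and at ZT22 formed 1 run of neighbouring title numbers each, as did 5 of 6 at ZT14 and 4 of 6 at ZT18, so their p are too small where runs resemble one another. Under light feeding on chow it was lower at ZT14 (log2FC -1.02, exact p = 0.00794, adjusted p = 0.0317) and ZT22 (-0.78, exact p = 0.00216, adjusted p = 0.0173), below all ad libitum libraries in 5 of 5 and 6 of 6 libraries, and higher at ZT2 (1.26, exact p = 0.0101, adjusted p = 0.0346), above all of them in 2 of 5. On HFD it was lower at ZT14 (-0.91), ZT18 (-0.57) and ZT22 (-0.38), below all ad libitum libraries in 6 of 6, 5 of 5 and 5 of 6 libraries (adjusted p = 0.0173, 0.0173 and 0.0208, exact tests), and higher at ZT2 (0.90, adjusted p = 0.0208, exact test), above all of them in 5 of 5. Under dark feeding none of the 12 exact tests passed the adjustment, the smallest adjusted p being 0.135.

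The 11 other clock genes of the panel placed 153 of 200 libraries nearest to the mean profile of their own time, and 114 nearest to that of their own group and time. The mean absolute log2 distance to the own profile had a median of 0.2 and a maximum of 0.8. Of the 4 libraries whose Per2 stood apart, 1 was nearest to its own group and time, chow light feeding replicate 8 (0.18). Chow ad libitum replicate 10, labelled ZT2, lay nearest to chow dark feeding at ZT22 (0.21, against 0.31 to its own profile), and replicate 13, labelled ZT6, nearest to chow ad libitum at ZT10 (0.19 against 0.5). Chow light feeding replicate 16, labelled ZT6, lay nearest to chow dark feeding at ZT22 (0.21 against 0.24).

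Myh9l1, a locus named for its likeness to a nonmuscle myosin heavy chain, was either absent or plainly present in most libraries. It had 0 counts in 83 of 200 libraries, at least 10 CPM in 91 and values between these in 26. The libraries with at least 10 CPM were 19 of 34 in chow ad libitum, 23 of 33 in chow dark feeding and 23 of 33 in chow light feeding, and 8 of 34, 11 of 33 and 7 of 33 in the HFD groups in the same order. Their median level lay between 22.7 and 38.6 CPM in every group. The log2FC between diets was -1.68, -1.79 and -2.36 under ad libitum, dark and light feeding (SE 0.57, 0.53 and 0.58; adjusted p = 0.0279, 0.0045 and 0.000635), and no explanation was tested.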
